A study of Mus musculus with 12 samples.

How the data were processed

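Gene expression was measured by RNA sequencing in 12 libraries from 2 mouse cell lines, 6 per line. AML12 is a hepatocyte line, and iWAT is described by its labels as a white adipocyte line. In each line 3 libraries came from cells given 50 µM diethyl phthalate (DEP) for 48 h, starting at confluence, and 3 from DMSO controls. The sample titles name DMSO and DEP, while the treatment field names only the medium, with or without DEP. Per the labels, RNA was taken with a mirVana kit, passed a quality minimum, and was made into stranded total RNA libraries. Reads were trimmed with Trimmomatic and aligned with HISAT2 to the GRCm39 mouse genome. The sources used here give no tool versions, and they name neither the counting tool nor its annotation.

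The deposited values were FPKM per gene, 1 table per line, with 27742 genes for AML12 and 29092 for iWAT. Genes were given as Ensembl identifiers. Symbols came from GENCODE M21, which matched 26378 identifiers (95.1%) in AML12 and 27621 (94.9%) in iWAT. That annotation belongs to another genome build (GRCm38), so it served for symbols and exon lengths only, and no coordinates are given. An FPKM value is a number of reads times a constant set by the library total and the gene's length. With the annotated exon length this gave whole numbers of reads, within 0.001, for 89.4% of the AML12 and 89.3% of the iWAT genes, and a search over lengths recovered the reads of 1565 and 1625 more. The recovered share of all reads was 99.99% in AML12 and 99.98% in iWAT. The files do not say whether the unit counted is a read or a read pair. Totals of 42845105 to 54585090 reads per library made 1 read in a 1-kb gene worth 0.0183 to 0.0233 FPKM. Such floors cover counting error only. The largest changes in small RNAs are therefore given with their reads.

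The tests were fixed before the data were examined. Within each line DEP was compared with DMSO by limma on log2(FPKM + 1), with empirical Bayes moderation that follows the mean level. Genes with at least 0.5 FPKM in at least 3 libraries of the line were tested. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Log2 fold changes on this scale understate the ratio of genes near or below 1 FPKM. The difference between the lines was tested as the interaction of line and treatment in a joint limma fit of all 12 libraries, over genes present in both tables with at least 0.5 FPKM in any 3 libraries. It is given as the AML12 log2 fold change minus the iWAT one.

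Gene lists, 35 in number, were fixed before the tables were opened and cover lipid and glucose metabolism, nuclear receptor and stress responses, inflammation, the cell cycle and cell type markers. Lists with at least 5 tested members were compared with all other tested genes by camera in limma, with a preset correlation of 0.01 between genes, and adjusted over the lists of that comparison. Camera was repeated with the correlation estimated from the data, and fry, which asks whether a list's genes move on balance 1 way, was run beside it. The counts of called members are given over all genes tested and adjusted over the list alone. Overlap between the lines was tested by Fisher's exact test, two-sided, over the genes tested in each line.

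The rule for naming genes was as follows. The 10 largest rises and 10 largest falls were taken among called genes with at least 1 FPKM in the higher group and no overlap between groups. Up to 4 called members with the smallest p were added from each list, then a fixed set of metabolic and stress genes, and the 10 genes with the smallest p for the difference between the lines. Symbols for unnamed gene models were left out.

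The procedure was tested on simulated data drawn with the libraries' means, totals and median replicate spread, with 200 genes changed, 50 at each of 4 sizes. In AML12 it called 35 of 50 genes changed 1.25-fold, 42 at 1.5-fold, 46 at 2-fold and 49 at 4-fold, with 8 false calls. In iWAT the counts were 37, 43, 47 and 50, with 11 false calls. For the difference between the lines they were 28, 41, 46 and 48, with 7 false calls. In simulated data without any change, 0 of 12811 genes and 0 of 28 lists were called in AML12, and 1 of 13382 genes and 0 of 26 lists in iWAT. Simulated genes varied independently, so this gives no error rate for lists of correlated genes.

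Nothing in the labels says that replicates were separate cultures. If they were not, the p-values measure only the spread between these libraries. The alternatives were other pseudocounts, filters, scalings and thresholds, a replicate block, a joint fit of both lines, leaving out each library, summing genes that share a symbol, and voom in limma on the recovered reads. Alternatives chosen for deposited counts were not run, since the files hold none. Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.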

Results

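Transcriptomes were measured in 2 mouse cell lines exposed to diethyl phthalate (DEP), a phthalate ester used as a plasticizer and solvent, in a series on DEP and metabolism-related disease. AML12 hepatocytes and iWAT cells each gave 3 DEP libraries (50 µM, 48 h) and 3 DMSO control libraries. Totals ran from 42845105 to 46232482 reads in AML12 DMSO, 49249612 to 52915505 in AML12 DEP, 50035049 to 54585090 in iWAT DMSO and 47735539 to 49059544 in iWAT DEP, so that depth differed with treatment in opposite directions in the lines. Levels below are means of 3 libraries in FPKM, with SD where given, and log2 fold changes (DEP over DMSO) carry their standard error where given.

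AML12 controls carried transcripts of simple epithelium and some of liver, with 14 of 25 hepatocyte markers above the filter. Krt8 and Krt18, the keratins of simple epithelia, stood at 1270 ± 11.5 and 1468 ± 13.5 FPKM. Krt19, a bile duct keratin, stood at 1008 ± 8.17 FPKM, Trf, which encodes the plasma iron carrier transferrin, at 392 ± 4.09 FPKM, and Hnf4a, a hepatocyte transcription factor, at 88.5 ± 1.21 FPKM. Alb, encoding serum albumin, reached 25.9 ± 0.480 FPKM. Other liver transcripts were near 0, such as Fga (fibrinogen) at 0.0520 FPKM and Apoc3 (an apolipoprotein) at 0.103 FPKM, with 21 and 14 reads over the 3 control libraries, and the urea cycle gene Ass1 had 0 reads in them. In iWAT controls the adipogenic receptor gene Pparg stood at 9.84 ± 0.493 FPKM, the lipoprotein lipase gene Lpl at 8.46 FPKM and the fatty acid carrier gene Fabp4 at 1.63 ± 0.0496 FPKM. Transcripts of mature fat cells were near 0 in those controls, with Adipoq (adiponectin) at 0.0184 FPKM and Plin1 (perilipin) at 0.00285 FPKM, 4 and 2 reads over the 3 libraries. The mesenchymal genes Pdgfrb (a growth factor receptor) and Acta2 (smooth muscle actin) stood at 22.7 ± 0.683 and 129 ± 2.67 FPKM.

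In AML12 cells DEP was accompanied by higher expression of genes for DNA replication, mitosis and cholesterol synthesis, and by lower expression of genes for antioxidant defence, xenobiotic metabolism, glycolysis and the hypoxia response. Tk1, which encodes the thymidine kinase of nucleotide salvage, rose from 10.1 ± 0.185 to 17.2 ± 0.535 FPKM (log2 fold change 0.71 ± 0.03, adjusted p = 2.08e-05). Acat2, an enzyme of acetyl-CoA use in sterol synthesis, rose from 16.3 ± 0.607 to 26.0 ± 0.824 FPKM (0.65 ± 0.04, adjusted p = 4.75e-05). Ugt2b34 (ENSMUSG00000029260), a glucuronosyltransferase gene, fell from 148 ± 2.55 to 55.8 ± 1.55 FPKM (-1.39 ± 0.03, adjusted p = 1.74e-06). Aldh3a1 (ENSMUSG00000019102), an aldehyde dehydrogenase gene, fell from 279 ± 5.07 to 120 ± 0.347 FPKM (-1.21 ± 0.02, adjusted p = 1.68e-06).

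Cell cycle genes rose nearly as a block. Of 26 genes of S phase and DNA replication, 25 rose and none fell, over all genes and adjusted over the list alone, with a median of 0.54 (adjusted p = 5.77e-14). Mcm6, a subunit of the replicative helicase, rose from 26.7 to 40.2 FPKM, and Prim1, a DNA primase subunit, from 6.74 to 11.5 FPKM. Of 24 genes of G2 and mitosis, 23 rose and none fell, and 24 rose adjusted over the list alone (median 0.43, adjusted p = 3.16e-11). The proliferation marker Mki67 rose from 12.5 ± 0.0857 to 20.9 ± 0.495 FPKM (0.70 ± 0.03), and Birc5 (survivin) from 12.8 to 19.3 FPKM.

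Cholesterol synthesis and uptake genes, targets of the sterol-regulated transcription factor SREBP2, rose in 22 of 25 cases and fell in none, over all genes and adjusted over the list alone (median 0.34, adjusted p = 3.82e-09). Cyp51, lanosterol demethylase, rose from 20.8 to 31.3 FPKM, and Hmgcs1, which makes HMG-CoA, from 24.1 to 33.6 FPKM. Fatty acid and triglyceride synthesis genes went both ways, with 11 of 19 up and 6 down, also adjusted over the list alone, and the list did not pass (adjusted p = 0.330). Within it Scd2, a stearoyl-CoA desaturase, rose from 406 to 538 FPKM, the lipogenic regulator Srebf1 from 35.2 to 46.2 FPKM and fatty acid synthase Fasn from 24.4 to 30.7 FPKM, while Scd1 fell by 0.09 on the log2 scale. Hepatocyte markers rose in 8 of 14 cases and fell in 1, with the same counts adjusted over the list alone (median 0.23, adjusted p = 0.0182), and the list had an adjusted p = 0.135 with an estimated correlation. Apob, the structural protein of very-low-density lipoprotein, rose from 3.03 ± 0.158 to 8.20 ± 0.173 FPKM (1.19 ± 0.04), Alb from 25.9 to 32.0 FPKM and Hnf4a from 88.5 to 109 FPKM.

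Detoxification genes fell. Targets of the oxidant-responsive factor NRF2 fell in 17 of 23 cases and rose in 1, over all genes and adjusted over the list alone (median -0.38, adjusted p = 1.42e-09). Gsta2, a glutathione transferase, fell from 60.5 ± 3.38 to 25.1 ± 0.734 FPKM (-1.24 ± 0.04), Gclc, the catalytic subunit for glutathione synthesis, from 202.4 to 138 FPKM, and Nqo1, a quinone reductase, from 5.36 to 3.24 FPKM. All 7 tested targets of the aryl hydrocarbon receptor (AHR) fell, also adjusted over the list alone (median -0.56, adjusted p = 8.08e-06), among them the monooxygenase gene Cyp1a1, from 2.12 ± 0.302 to 0.356 ± 0.109 FPKM (adjusted p = 0.000201, with a mean of 50 reads per DEP library). Targets of the drug receptors CAR and PXR fell in 5 of 10 cases and rose in 2, and 6 fell adjusted over the list alone (median -0.34, adjusted p = 0.0104). That list had an adjusted p = 0.149 with an estimated correlation. Abcc2, a canalicular export pump, fell from 43.6 to 22.8 FPKM, and Cyp3a13, a cytochrome P450, from 29.2 to 16.7 FPKM.

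Glycolysis and hypoxia response genes fell in 20 of 28 cases and rose in 3, and 21 fell adjusted over the list alone (median -0.32, adjusted p = 3.82e-09). Ndrg1, a hypoxia-induced gene, fell from 35.0 ± 0.252 to 18.5 ± 0.324 FPKM (-0.88 ± 0.02), and Bnip3, a mitophagy receptor, from 44.1 to 26.2 FPKM. Targets of ATF4, the factor of the integrated stress response, fell in 15 of 24 cases and rose in 3, or in 4 adjusted over the list alone (median -0.15, adjusted p = 5.27e-06). Ddit3, which encodes the stress factor CHOP, fell from 15.3 ± 0.588 to 5.06 ± 0.244 FPKM (-1.43 ± 0.04), Trib3, a pseudokinase, from 49.3 to 28.4 FPKM, and Slc7a11, the cystine importer, from 20.01 to 13.6 FPKM. Endoplasmic reticulum chaperone and unfolded protein response genes fell in 9 of 19 cases and rose in none, also adjusted over the list alone (adjusted p = 0.00101, and adjusted p = 0.0611 with an estimated correlation). The chaperone gene Hspa5 fell from 171 to 128 FPKM.

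Smaller shifts lost their call with an estimated correlation. Ribosomal protein genes fell in 25 of 40 cases, and in 28 adjusted over the list alone, with none up (median -0.15, adjusted p = 5.21e-09, and adjusted p = 0.401 with an estimated correlation). Rpl4, a large-subunit protein, fell by 0.21 on the log2 scale. Gluconeogenesis genes fell in 7 of 9 cases, also adjusted over the list alone (adjusted p = 0.00245, and adjusted p = 0.0804 with an estimated correlation), with the mitochondrial carboxykinase Pck2 at -0.30. Circadian clock genes fell in 8 of 15 cases and rose in 2, also adjusted over the list alone (adjusted p = 0.00732, and adjusted p = 0.135 with an estimated correlation), and the clock output factor Dbp fell from 13.9 to 5.26 FPKM. Glucocorticoid receptor targets fell in 6 of 12 cases and rose in 1, also adjusted over the list alone (adjusted p = 0.0249, and adjusted p = 0.135 with an estimated correlation), with the hormone-induced Klf9 at -0.43.

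Chemokine genes were among the other AML12 genes that changed. Ccl9, a macrophage attractant, rose from 53.1 ± 1.71 to 138 ± 0.563 FPKM (1.36 ± 0.03, adjusted p = 1.74e-06), and Ccl2, the main monocyte attractant, from 203.8 ± 1.23 to 374 ± 10.9 FPKM (0.87 ± 0.02). Lcn2, an iron-sequestering acute phase gene, fell from 71.6 to 35.0 FPKM. The inflammation list as a whole went both ways, with 6 of 17 up and 7 down, or 6 and 8 adjusted over the list alone (adjusted p = 0.359). The mast cell protease gene Mcpt8 rose from 1.12 to 4.62 FPKM, cardiac troponin T (Tnnt2) from 4.02 to 10.6 FPKM, Ranbp3l from 0.854 to 3.27 FPKM, and S100a7a and Gimd1 by 1.02 and 1.01 on the log2 scale. The largest falls also held Ugt2b35, a close paralog of Ugt2b34, at -1.40, Olfm4 (olfactomedin) at -1.41, the lipid droplet enzyme Hsd17b13 at -1.39, the inflammasome-related Nlrp10 at -1.38 and the collagenase Mmp13 at -1.21. FPKM cannot show how reads were divided between paralogs such as Ugt2b34 and Ugt2b35 or Gsta1 and Gsta2. The small RNAs Snord98, Mir192 and Snord43 rested on 4 to 16, 1.67 to 12.3 and 12.3 to 38.3 reads per library, DMSO to DEP, and their calls ended without some single libraries, with an adjusted p of up to 0.0902 for AML12 Snord98 (without DEP replicate 2), 0.0777 for AML12 Mir192 (without DMSO replicate 3) and 0.116 for AML12 Snord43 (without DEP replicate 2).

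The other AML12 lists did not pass the test. AML12 PPAR alpha targets fell in 6 of 12 cases and rose in 2, also adjusted over the list alone (adjusted p = 0.0538, but 0.0315 without DEP replicate 3 and 0.0436 without DMSO replicate 2). Fatty acid oxidation genes fell in 5 of 21 and rose in 1, also adjusted over the list alone (adjusted p = 0.0970). Interferon response genes had 3 of 9 members down, also adjusted over the list alone (adjusted p = 0.0865). For p53 targets 8 of 19 were up and 4 down, or 9 and 4 adjusted over the list alone (adjusted p = 0.658), with the cell cycle inhibitor Cdkn1a up from 45.0 to 51.3 FPKM and Ephx1, an epoxide hydrolase, down from 159 to 93.1 FPKM. Extracellular matrix genes had 6 of 12 up and 5 down, or 7 and 5 adjusted over the list alone (adjusted p = 0.658), with a positive median and a negative mean. Adjusted p-values were 0.212 for the AML12 nuclear-encoded respiratory chain (0.0218 without DEP replicate 1), 0.658 for adipocyte markers, LXR targets and cholangiocyte markers, 0.668 for lipolysis and 0.983 for insulin signalling. Mitochondrial mRNAs as a list did not move 1 way (adjusted p = 0.523). Of 13, 1 rose and 3 fell, also adjusted over the list alone, while 39.2% of all tested AML12 genes were called. Fry for changes in either direction had an adjusted p = 1.67e-06. It does not single this list out, since every AML12 list passed that test, with 0.0209 the highest adjusted p. The respiratory complex I subunit mt-Nd1 rose from 3740 to 4906 FPKM, while its fellow subunits mt-Nd5 and mt-Nd6 fell from 1462 to 1070 and from 920 to 657 FPKM, and mt-Co1, of complex IV, fell by 0.32 on the log2 scale. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1, chosen after their values were seen, rose by 0.65 and 0.48 on the log2 scale. In iWAT mt-Rnr2 rose by 0.14 and mt-Nd6 fell by 0.13. Such RNAs can also vary with RNA quality and with the removal of ribosomal RNA, which were not analysed here. Pparg, the adipogenic receptor, was at 0.578 and 0.615 FPKM (adjusted p = 0.734). Lists with fewer than 5 tested members were not tested; they were the thermogenic, preadipocyte, bile acid, leukocyte, endothelial, stellate and skeletal muscle lists.

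By limma, 5074 of 12929 tested AML12 genes (39.2%) were called, 3092 up and 1982 down. Changes were small: the median size among called genes was 0.23, and 41 genes, 14 up and 27 down, changed at least 2-fold. In 6720 genes (52.0%) the groups did not overlap, against 10% by chance. Centred on each library's median, 2357 genes were up and 2545 down, so the excess of rises depended on the scaling. Camera called 14 of 28 lists, 4 up and 10 down, and 7 of them held with an estimated correlation. Their adjusted p then ran only from 0.0130, for S phase among others, to 0.0330 for AHR targets, far above the values with the preset correlation.

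**Figure D1:**
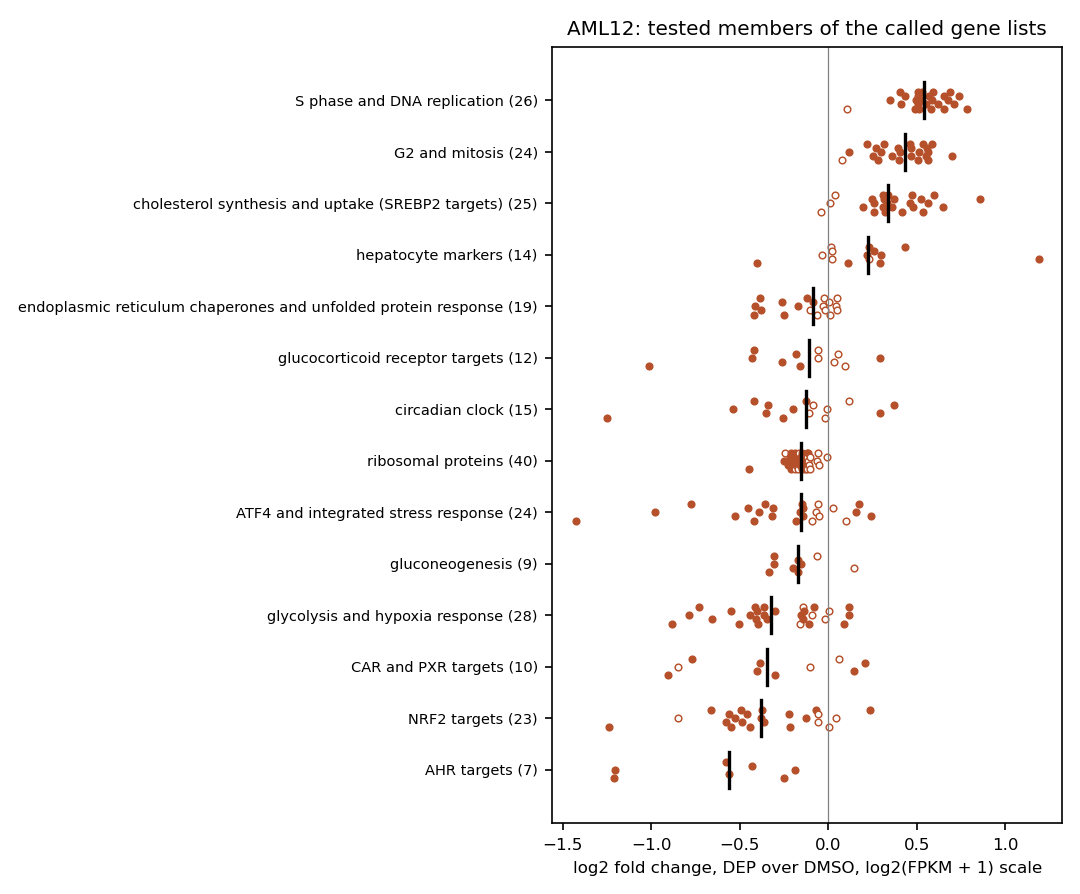
Log2 fold changes (DEP over DMSO) of the tested members of the 14 called gene lists in AML12, 1 point per gene (filled if called), with a bar at the median of each list. The S phase list has a median of 0.54 and the NRF2 list a median of -0.38.

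**Figure D2:**
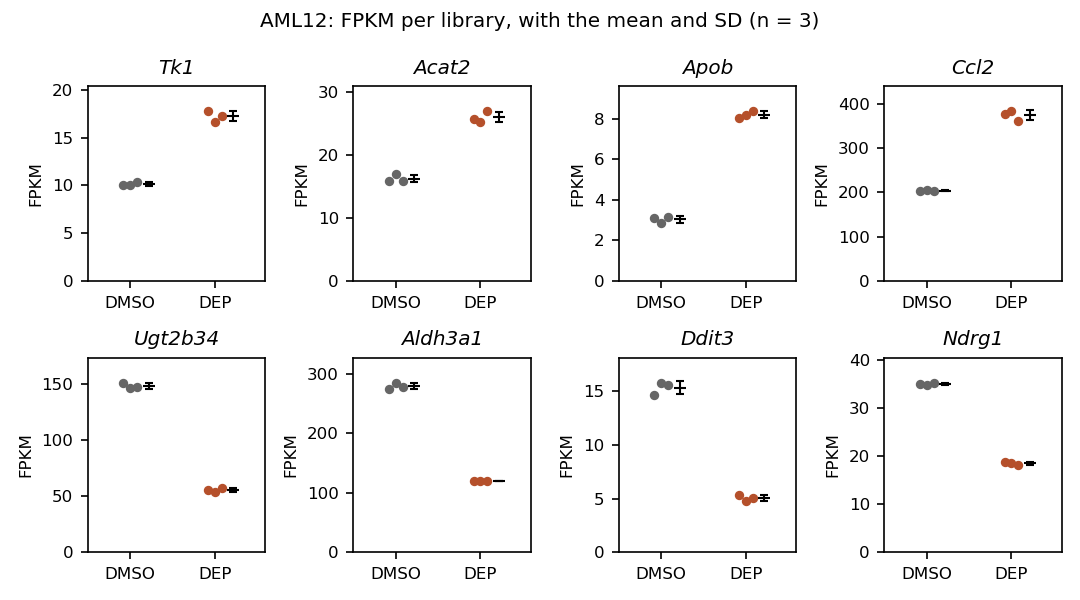
FPKM of 8 named genes in the 3 DMSO and 3 DEP libraries of AML12, 1 point per library, with group mean and SD. Tk1 and Ccl2 are higher with DEP, and Aldh3a1 falls from a mean of 279 to 120 FPKM.

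In iWAT cells the interferon response was lower with DEP across its whole list, together with inflammatory, extracellular matrix, mitotic and cholesterol synthesis genes, while p53 targets were higher. The comparison asks the same question in cells of adipose origin. Gbp3 (ENSMUSG00000028268), an interferon-induced GTPase gene, fell from 33.9 ± 0.389 to 16.2 ± 0.367 FPKM (-1.02 ± 0.02, adjusted p = 1.87e-05). Saa3 (ENSMUSG00000040026), an acute phase gene, fell from 7.47 ± 0.181 to 2.63 ± 0.223 FPKM (-1.22 ± 0.05, adjusted p = 5.78e-05). Cdkn1a, the p53-induced cell cycle inhibitor, rose from 43.5 ± 1.01 to 64.1 ± 2.75 FPKM (0.55 ± 0.03, adjusted p = 0.000259).

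All 27 tested interferon response genes fell, over all genes and adjusted over the list alone (median -0.56, adjusted p = 2.60e-38). Ifit3, an antiviral translation inhibitor, fell from 112 ± 3.91 to 60.6 ± 1.58 FPKM (-0.87 ± 0.03), Rsad2, the antiviral enzyme viperin, from 52.99 to 30.4 FPKM and Irf7, which amplifies interferon production, from 35.3 to 22.1 FPKM. Gbp2 fell by 0.96 on the log2 scale, as did Zbp1, a sensor of Z-form nucleic acid. Gbp2 and Gbp3, like Ifit3 and its near copy, are close paralogs whose reads FPKM cannot part. Inflammation genes fell in 12 of 19 cases and rose in 1, or in 15 and 2 adjusted over the list alone (median -0.37, adjusted p = 6.96e-13). Cxcl10 and Cxcl5, chemokines for T cells and neutrophils, fell from 144 to 95.7 and from 23.9 to 13.5 FPKM. Il6, the interleukin-6 gene, fell from 4.22 ± 0.143 to 2.32 ± 0.279 FPKM (-0.66 ± 0.07), and Ccl2 from 480 to 356 FPKM (-0.43 ± 0.03).

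Targets of p53, the DNA damage factor, rose in 17 of 19 cases and fell in none, also adjusted over the list alone (median 0.27, adjusted p = 6.96e-13). Phlda3, an inhibitor of AKT signalling, rose from 47.5 ± 0.855 to 63.6 ± 1.48 FPKM (0.41 ± 0.02), and cyclin G1 (Ccng1) from 58.9 to 76.1 FPKM. Genes of G2 and mitosis fell in 9 of 24 cases, and in 17 adjusted over the list alone, with none up (median -0.10, adjusted p = 2.41e-07). By camera with an estimated correlation that list had an adjusted p = 0.0420. Ccnb2, a mitotic cyclin, fell from 51.2 to 42.5 FPKM and the mitotic kinase Plk1 from 25.02 to 20.6 FPKM. S phase genes had 6 of 26 up and 2 down, also adjusted over the list alone (adjusted p = 0.0954).

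Extracellular matrix and TGF beta response genes fell in 16 of 24 cases, or in 18 with 1 up adjusted over the list alone (median -0.18, adjusted p = 6.96e-13). By camera with an estimated correlation that list had an adjusted p = 0.0457. Lox, which crosslinks collagen, fell from 23.2 to 14.6 FPKM and the collagen chain Col1a2 from 31.5 to 24.1 FPKM. Acta2 fell from 129 to 93.4 FPKM. Preadipocyte markers had 1 of 10 up and 4 down, or 4 and 5 adjusted over the list alone (adjusted p = 0.407), with Pdgfra, a receptor of adipose progenitors, down from 4.40 to 2.99 FPKM and the stem cell antigen Ly6a down from 74.1 to 48.2 FPKM.

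Cholesterol synthesis genes fell in 10 of 25 cases and rose in 1, or 14 and 1 adjusted over the list alone (median -0.17, adjusted p = 2.05e-05). By camera with an estimated correlation that list had an adjusted p = 0.0420. Sqle, squalene epoxidase, fell from 14.1 to 11.1 FPKM, the sterol oxidase gene Msmo1 from 18.1 to 14.6 FPKM and Hmgcs1 from 11.8 ± 0.630 to 9.26 ± 0.497 FPKM (-0.32 ± 0.05, adjusted p = 0.0128). Fatty acid oxidation genes fell in 4 of 21 cases, or in 6 with 1 up adjusted over the list alone (adjusted p = 0.00224, and adjusted p = 0.0762 with an estimated correlation), with the thiolase Acaa2 at -0.23. Of 6 tested adipocyte markers 1 fell, Lpl, from 8.46 to 6.38 FPKM, and 2 fell adjusted over the list alone (adjusted p = 0.0226, and adjusted p = 0.165 with an estimated correlation). Without DEP replicate 1 the list of iWAT adipocyte markers had an adjusted p = 0.0557. Pparg was at 9.84 and 9.40 FPKM (adjusted p = 0.476) and Fabp4 at 1.63 and 1.28 FPKM (adjusted p = 0.0794). Plin2, a lipid droplet coat protein, fell from 57.6 to 48.7 FPKM (iWAT Plin2 had an adjusted p = 0.0508 without DEP replicate 2), Angptl4, an inhibitor of lipoprotein lipase, from 5.12 to 3.14 FPKM, Scd2 from 105 to 88.4 FPKM and Scd1 from 36.6 to 32.2 FPKM. Fatty acid and triglyceride synthesis genes as a list had 1 of 18 up and 5 down, or 2 and 6 adjusted over the list alone (adjusted p = 0.0647). The called rise was that of Fasn, by 0.11 on the log2 scale (adjusted p = 0.0323).

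ATF4 targets rose in 8 of 24 cases and fell in none, or 11 and 1 adjusted over the list alone (median 0.05, adjusted p = 0.000495, and adjusted p = 0.165 with an estimated correlation). Atf3, a stress-induced factor, rose from 17.0 to 21.8 FPKM, and Ppp1r15a, which reverses eIF2 phosphorylation, from 70.2 to 82.9 FPKM. The level of iWAT Ddit3 was 84.9 and 93.2 FPKM (adjusted p = 0.0595, but 0.0483 without DEP replicate 3). Circadian genes rose in 3 of 16 cases and fell in none, or 6 and 1 adjusted over the list alone (adjusted p = 0.00450, and adjusted p = 0.0892 with an estimated correlation), with the repressor Nr1d1 at 0.28. Glucocorticoid receptor targets fell in 4 of 12 cases, or 6 with 2 up adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.239 with an estimated correlation), with the kinase Sgk1 at -0.36. Nuclear-encoded respiratory chain genes fell in 2 of 29 cases, also adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.431 with an estimated correlation), with the subunit gene Ndufa4 at -0.18 (iWAT Ndufa4 had an adjusted p = 0.105 without DMSO replicate 3). The iWAT nuclear-encoded respiratory chain list lost its call without DEP replicate 3 (adjusted p = 0.0905) and without DMSO replicate 3 (adjusted p = 0.0584).

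Other named iWAT genes included Gas1, a growth arrest gene, which fell from 18.0 ± 0.463 to 8.35 ± 0.521 FPKM (-1.03 ± 0.04), Slfn2, a regulator of T cell quiescence, which fell from 5.09 to 2.06 FPKM, the chemokine Ccl8 at -0.98 and the small GTPase Rasl11a at -0.94. Klf2, a flow-responsive factor, rose by 0.57 ± 0.04 on the log2 scale, the GTPase Rhob from 66.9 to 98.3 FPKM and the Nogo receptor Rtn4r from 3.47 to 5.84 FPKM, while Prr32 and Klrg2 rose by 0.48 and 0.45 on the log2 scale. Rps27a-ps2, at -1.14, is a ribosomal pseudogene whose reads its parent gene can supply. Several of the largest changes rested on few reads per library. Mir7651 had 0 reads in DMSO and a mean of 5 in DEP, Scgb1a1 had 2 and 33.3, Snora47 6.33 and 19, Snord35a 8 and 16.7, and Mir1964 6 and 0.667. Without DMSO replicate 3 the adjusted p was 0.0654 for iWAT Scgb1a1, 0.133 for iWAT Snora47, 0.0846 for iWAT Mir1964 and 0.0924 for iWAT Prr32, and without DEP replicate 1 it was 0.0958 for iWAT Snord35a. Leaving out some of the other libraries also ended these calls.

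NRF2 targets had 1 of 22 up and 2 down in iWAT, or 3 and 3 adjusted over the list alone (adjusted p = 0.878), with Hmox1, heme oxygenase, up from 205 to 229 FPKM and Nqo1 at 18.7 and 19.2 FPKM (adjusted p = 0.649). Ribosomal protein genes had no called member among 40, nor any adjusted over the list alone (adjusted p = 0.944). The remaining lists did not pass either, with adjusted p-values of 0.270 for PPAR alpha targets, 0.353 for LXR targets and mitochondrial mRNAs, 0.551 for endoplasmic reticulum chaperones, 0.621 for gluconeogenesis, 0.622 for glycolysis and hypoxia, 0.623 for insulin signalling, 0.756 for thermogenic genes and 0.944 for lipolysis. The AHR, CAR and PXR, hepatocyte, bile acid, leukocyte, endothelial, cholangiocyte, stellate and skeletal muscle lists had fewer than 5 tested members. Among AHR targets Cyp1b1, a monooxygenase, fell from 30.2 to 23.5 FPKM.

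By limma, 1152 of 13482 tested iWAT genes (8.54%) were called, 543 up and 609 down, with 9 changed at least 2-fold. In 4196 genes (31.1%) the groups did not overlap, against 10% by chance. The count was 503 with a replicate block, 511 (without DMSO replicate 3) to 687 without 1 library, 664 with no filter on low genes and 1992 with voom. The balance of rises and falls turned with voom (1052 up, 940 down) and with quantile normalization (600 up, 578 down). Camera called 12 of 26 lists, 3 up and 9 down, and 6 held with an estimated correlation. Their adjusted p then ran only from 0.0053 for the interferon response to 0.0457 for extracellular matrix genes.

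**Figure D3:**
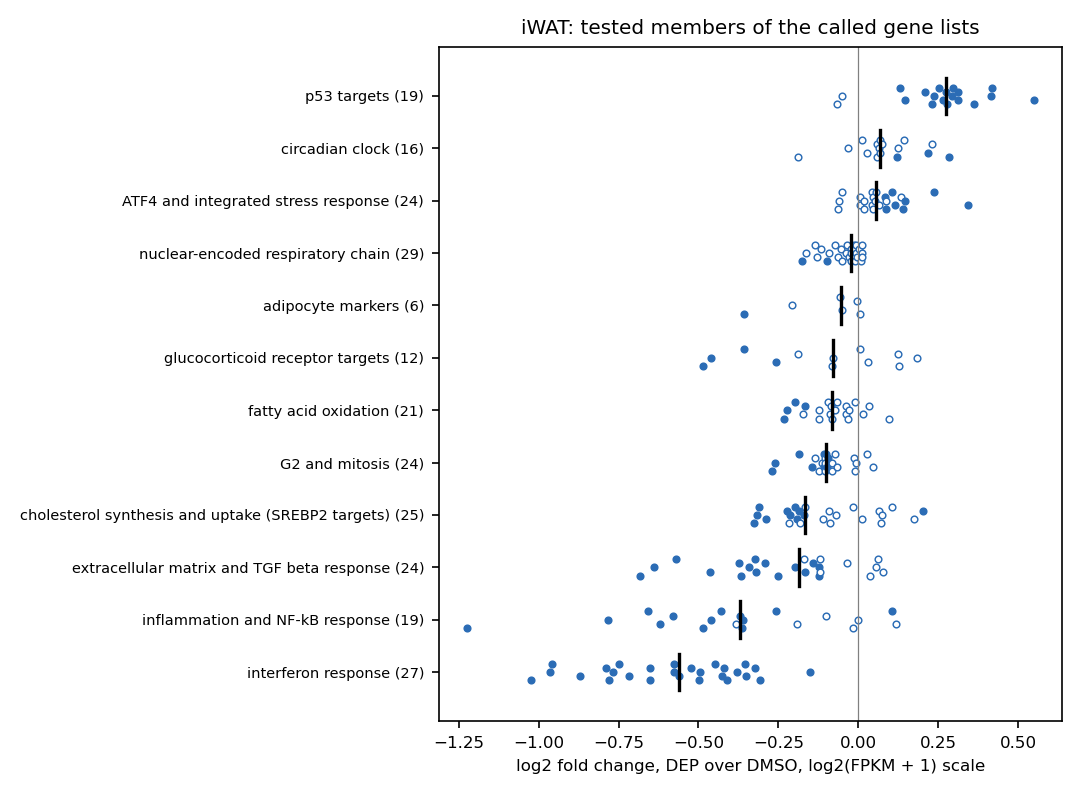
Log2 fold changes (DEP over DMSO) of the tested members of the 12 called gene lists in iWAT, 1 point per gene (filled if called), with a bar at the median of each list. All 27 interferon response genes lie below 0 and the p53 list has a median of 0.27.

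**Figure D4:**
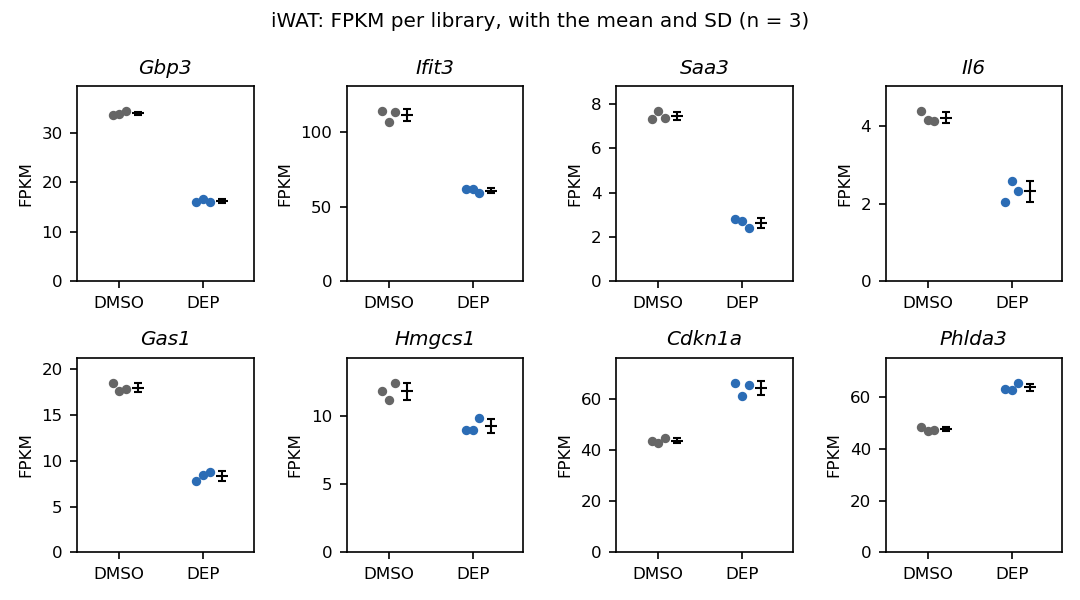
FPKM of 8 named genes in the 3 DMSO and 3 DEP libraries of iWAT, 1 point per library, with group mean and SD. Gbp3 falls from a mean of 33.9 to 16.2 FPKM, and Cdkn1a rises from 43.5 to 64.1 FPKM.

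The responses to DEP differed between the lines for several gene groups, and the lists for mitosis and cholesterol synthesis were called up in AML12 and down in iWAT. Cell cycle and cholesterol synthesis genes responded more positively in AML12 than in iWAT, and NRF2, ATF4, hypoxia and p53 genes more negatively. The p53 list did not fall in AML12, where its median was 0.07 without a call, but rose in iWAT, with a median of 0.27. The median difference (AML12 minus iWAT) was 0.51 for S phase genes (adjusted p = 2.43e-18), 0.52 for G2 and mitosis (adjusted p = 2.73e-18), 0.50 for cholesterol synthesis (adjusted p = 1.94e-12), -0.41 for NRF2 targets (adjusted p = 2.06e-09), -0.22 for ATF4 targets (adjusted p = 3.16e-09), -0.32 for glycolysis and hypoxia (adjusted p = 2.51e-10) and -0.26 for p53 targets (adjusted p = 8.62e-07). Hmgcs1 rose in AML12 and fell in iWAT, and Ccl2 did the same, with a difference of 1.30 ± 0.04. Scd2, Spp1 (osteopontin) and Sparc (osteonectin), a desaturase and a pair of matrix proteins, also rose in AML12 and fell in iWAT, with differences of 0.65 ± 0.02, 0.67 ± 0.02 and 0.70 ± 0.03. Ndrg1 went the other way, with a difference of -1.15 ± 0.04.

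Among the 10 genes with the smallest p for the difference were also Ugt2b34 at -1.38 ± 0.04, the chemokine Ccl7 at 1.24 ± 0.04, Ddit3 at -1.56 ± 0.06, Ephx1 at -0.89 ± 0.03 and the autophagy receptor Sqstm1 at -0.55 ± 0.02. Sqstm1 stood at 197 and 143 FPKM in AML12 and at 397 and 425 FPKM in iWAT. The interaction in limma called 4283 of 14651 genes (29.2%), with 2575 more positive in AML12 and 1708 more negative. In 2911 of them the estimates had opposite signs, a count that includes estimates near 0. Among the genes tested in each line, 116 were called up in AML12 and down in iWAT, and 90 the reverse. Of 29 lists 18 differed, and 15 held with an estimated correlation, with adjusted p from 0.000211 for S phase to 0.0450 for endoplasmic reticulum chaperones. Some genes were near 0 in 1 line, where a difference reflects the other line alone. Among the 11399 genes tested in each line, a set chosen after the data were seen, 13 of 23 lists differed, and the difference ended for extracellular matrix genes (12 members, adjusted p = 0.438) and inflammation genes (15 members, adjusted p = 0.134). The AHR, CAR and PXR, and hepatocyte lists, with 3, 4 and 1 members tested in iWAT, were too small for that test.

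**Figure D5:**
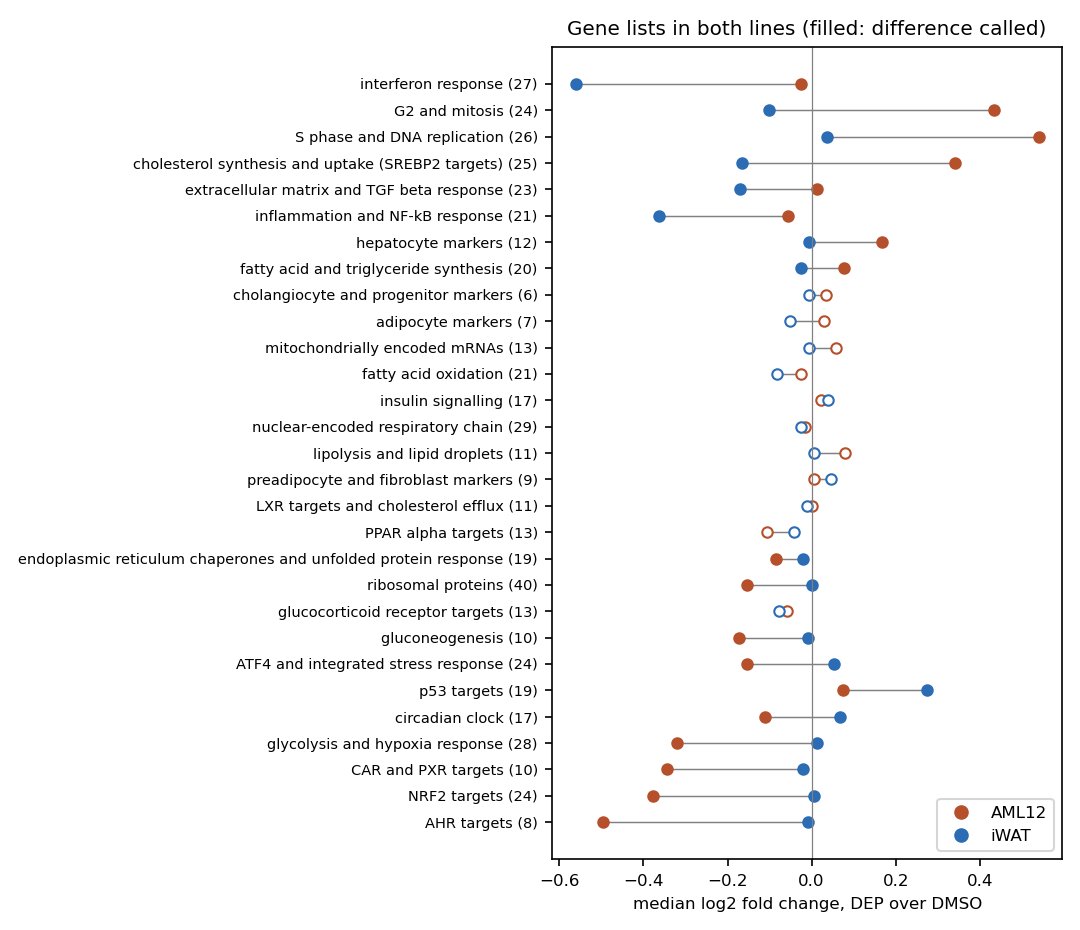
Median log2 fold change (DEP over DMSO) of each gene list in AML12 and in iWAT, 1 joined pair of points per list, filled where the difference was called. The cholesterol synthesis list has medians of 0.34 in AML12 and -0.17 in iWAT.

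Genes called in each line shared a direction more often than independence gives, for rises and for falls. Since genes do not vary independently, the exact tests of overlap, here and below, are descriptive only. Of the 11399 genes tested in each line 182 rose in both, against 125.8 expected (ratio 1.45, Fisher's exact p = 1.41e-08), and 124 fell in both, against 66.5 expected (ratio 1.86, Fisher's exact p = 7.50e-13). Genes up in AML12 and down in iWAT numbered 116, against 111.2 expected (exact p = 0.615, but 0.0394 without AML12 DEP replicate 2), and the reverse held for 90, against 75.2 expected (exact p = 0.0634). That last test passed under several alternatives, among them quantile normalization (exact p = 7.00e-05) and 7 of the 12 fits without 1 library. Lcn2 fell in both lines, by 1.01 and 0.49 on the log2 scale, and Ly6a by 0.48 and 0.61. Cdkn1a rose in both, by 0.19 and 0.55. Of 512 genes called in both, 306 (59.8%) moved the same way. Across all 11399 genes the fold changes had a Pearson r of 0.0192 and a Spearman rho of 0.0427, where genes are not independent replicates.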

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

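Of the tests in this part, the AML12 test by median centring, the leukocyte test and the restriction to genes tested in each line were chosen only after the result was seen.

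In AML12, S phase and mitosis genes rose with DEP while NRF2, AHR and hypoxia genes fell, and the DEP libraries were also the deeper ones. The recovered reads of the 6 libraries were thinned to the lowest total. Then 12894 genes were tested, 5026 were called and the S phase median was 0.54. FPKM already divides by the total, and no list checked moved by more than 0.0045. The pattern thus stood at equal totals, which argues against the number of reads itself as its cause. Anything else that differed along with depth cannot be told apart from DEP here. Fold changes followed gene length weakly across genes (Spearman rho 0.101), and with that trend removed the S phase median was 0.52, so the trend does not account for it either. Centring each library on its median moved the NRF2 median from -0.38 to -0.42. Centring shifts all genes of a library alike and the median gene stood at 0.03 before it, so that outcome was known beforehand. A scaling factor per library would move all its genes 1 way, whereas S phase genes rose and NRF2 genes fell. A faster-growing or less dense culture at harvest, or an action of DEP on these pathways, could each give the pattern, and neither was tested against the other.

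In iWAT, interferon and inflammation genes fell with DEP. After thinning the 6 libraries to the lowest total the interferon median was -0.56, as before, with 13449 genes tested and 1135 called. No list checked moved by more than 0.0040, so the number of reads itself does not account for the fall. For these genes too, anything else that differed along with depth cannot be told apart from DEP. A set of 12 leukocyte transcripts, of which 8 were in the table, summed to 1.09 FPKM in DMSO and 1.16 in DEP, while the interferon list lost 533 FPKM (from 1739 to 1206). The fixed macrophage and leukocyte list, with Cd68 at 10.9 and Cd14 at 5.13 FPKM in DMSO, summed to 17.1 FPKM in DMSO and 19.5 in DEP. Interferon transcripts carried by leukocytes among the DMSO cells thus do not account for the loss. These sums do not bear on any effect of such cells on the others. Without any 1 library at least 26 of the 27 members stayed called, and the list's adjusted p was at most 2.82e-34, so no single library carries the pattern. A lower interferon tone with DEP, or a higher one in the DMSO cultures for a reason unrelated to DEP, may underlie it, and the design gives no untreated culture that would tell them apart.

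Cholesterol synthesis genes rose with DEP in AML12 and fell in iWAT, and depth differed with treatment in opposite directions in the lines. With all 12 libraries thinned to the lowest total the median difference was 0.50, as before, and no list checked moved by more than 0.0093. Here as well the values argue against the number of reads itself, while anything else that went along with depth stays open. Quantile normalization left the iWAT median at -0.16 against -0.17 and the AML12 median at 0.31 against 0.34. As deposited, the median tested gene already stood at 0.032 in AML12 and 0.0075 in iWAT. Normalization could thus hardly move the list medians, so this outcome was largely known beforehand and gives no independent test of scaling. A sterol response that depends on the cell type or on its medium, which differed between the lines, may be at work and was not tested.

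For 18 of 29 gene lists the response to DEP differed between the lines by the interaction test, 8 with a higher and 10 with a lower response in AML12. Median differences (AML12 minus iWAT, log2) were 0.57 for the interferon response, 0.52 for G2 and mitosis, 0.51 for S phase, 0.50 for cholesterol synthesis, 0.28 for extracellular matrix, 0.25 for inflammation, 0.21 for hepatocyte markers and 0.11 for fatty acid and triglyceride synthesis. Negative medians were -0.49 for AHR targets, -0.41 for NRF2 targets, -0.34 for CAR and PXR targets, -0.32 for glycolysis and hypoxia, -0.27 for the circadian clock, -0.26 for p53 targets, -0.22 for ATF4 targets, -0.19 for gluconeogenesis, -0.15 for ribosomal proteins and -0.090 for endoplasmic reticulum chaperones. With an estimated correlation the call ended for ribosomal proteins (adjusted p = 0.360), fatty acid and triglyceride synthesis (adjusted p = 0.264) and hepatocyte markers (adjusted p = 0.0553). Only 9 interferon genes were tested in each line, and over these the median difference was 0.27 (adjusted p = 0.0156, and adjusted p = 0.0547 with an estimated correlation). AHR targets, CAR and PXR targets and hepatocyte markers had 3, 4 and 1 members tested in iWAT, so their differences rest mainly on genes near 0 there.

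Of the named genes with a test of the difference, 94 responded differently in the lines, 54 more positively and 40 more negatively in AML12, and 9 did not differ. Most of these genes were named for their responses in these same data, some for this very difference. Their count is therefore no evidence of a difference, and over all 14651 genes tested 29.2% differed. Of the 94, 62 were tested in each line. For sterol and fatty acid genes the difference was 0.78 for Cyp51, 0.78 for Hmgcs1, 0.61 for Msmo1, 0.58 for Acat2 and 0.57 for Sqle. The lipogenic and lipid handling genes gave 0.65 for Scd2, 0.39 for Srebf1, 0.21 for Fasn, 0.095 for Scd1, 0.49 for Plin2, 0.71 for Angptl4 and 0.18 for Acaa2. Genes of replication and mitosis differed by 0.80 for Tk1, 0.64 for Prim1 and 0.57 for Mcm6, and by 0.78 for Plk1, 0.65 for Mki67, 0.53 for Birc5 and 0.38 for Ccnb2. Chemokine and immune genes gave 1.55 for Ccl9, 1.30 for Ccl2, 1.24 for Ccl7, 0.83 for Cxcl5, 0.80 for Ccl8, 1.16 for Slfn2, 1.44 for Mcpt8 and -0.53 for Lcn2. Among secreted and surface proteins the values were 0.70 for Sparc, 0.67 for Spp1, 0.82 for S100a7a, -0.85 for Mmp13 and 0.13 for Ly6a. Stress response genes responded more negatively in AML12, with -1.56 for Ddit3, -1.21 for Ppp1r15a, -0.91 for Trib3, -0.86 for Gdf15, -0.65 for Atf3, -0.59 for Slc7a11, -0.47 for Hspa5 and -0.25 for Pck2. Antioxidant and hypoxia genes did likewise, with -1.15 for Ndrg1, -0.69 for Bnip3, -0.63 for Gclc, -0.62 for Nqo1, -0.44 for Fth1 and -0.37 for Hmox1. So did Ephx1, of the p53 list, at -0.89 and the autophagy receptor Sqstm1 at -0.55. For p53 targets and Rhob the differences were -0.36 for Cdkn1a, -0.33 for Ccng1, -0.35 for Rhob and -0.26 for Phlda3. Clock and hormone-responsive genes gave -1.32 for Dbp, -0.62 for Nr1d1, -0.24 for Klf9 and 0.45 for Sgk1. The remaining differences were -2.38 for Scgb1a1, 1.05 for Rps27a-ps2, -1.04 for Prr32, -1.02 for Mir7651, -0.25 for Rpl4 and 0.23 for Ndufa4. Scgb1a1, Mir7651, Rps27a-ps2, Scd1, Ly6a and Ndufa4 lost this call in 6 or more alternatives.

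For 18 genes the AML12 level was below the filter, so their difference reflects iWAT. Interferon and inflammation genes of this kind gave 1.17 for Saa3, 1.02 for Gbp3, 0.97 for Zbp1, 0.86 for Gbp2, 0.86 for Ifit3, 0.76 for Rsad2, 0.71 for Cxcl10, 0.64 for Il6 and 0.59 for Irf7. Mesenchymal and other genes gave 1.21 for Mir1964, 1.03 for Gas1, 0.84 for Rasl11a, 0.52 for Pdgfra, 0.44 for Acta2, 0.39 for Lpl, 0.38 for Col1a2, -0.43 for Klrg2 and -0.57 for Klf2. For 14 genes the iWAT level was below the filter, so their difference reflects AML12. Detoxification genes among them gave -1.39 for Ugt2b35, -1.38 for Ugt2b34, -1.32 for Cyp1a1, -1.22 for Gsta2, -1.18 for Aldh3a1, -0.88 for Abcc2, -0.81 for Cyp3a13 and -0.55 for Ugt1a6b. Hepatocyte genes and others gave -1.38 for Hsd17b13, 1.26 for Ranbp3l, 1.21 for Apob, 1.16 for Tnnt2, 0.32 for Hnf4a and 0.29 for Alb.

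Each line's 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In AML12 only 1 of the 10, the real one, gave 5074 genes, with 0 in the highest other split, where 184 to 379 genes had an unadjusted p below 0.05. In iWAT 1 of the 10 gave 1152 genes, again with 0 in the highest other and 366 to 531 at the unadjusted level. For lists, 1 of 10 splits gave as many as the real 14 in AML12, with 9 in the highest other, and 1 of 10 as many as the real 12 in iWAT, with 7 in the highest other. A wrong split sets 2 libraries of a treatment and 1 of the other against the reverse, so it keeps part of the treatment difference and adds the rest to the spread. The 6 to 9 lists called in wrong AML12 splits and the 1 to 7 in iWAT, or 0 in each with an estimated correlation, are therefore no count of false calls. Of the 100 pairs made of 1 split per line, only 1, the real pair, gave 306 genes called in the same direction in both lines, with 0 in the highest other. No wrong split called a gene, so every other pair had to give 0, and this count adds nothing to the splits within each line. For the difference between the lines 100 pairs were drawn. As many as 4283 genes with a different response arose in 2 pairs, the other being the real groups with the iWAT treatments exchanged (4732). As many as 18 lists arose in 3 pairs, with 20 in the highest other. These shares concern only a chance assignment in both lines at once. They do not exclude it in 1 line alone, nor do they test the difference itself. The 8 drawn pairs with the real AML12 groups and a wrong iWAT split, which keeps part of the iWAT difference, gave 2958 to 3120 genes and 13 to 18 lists.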

How the results depend on the processing

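The tests with voom on recovered reads, the filter of 10 recovered reads, the restriction to genes tested in each line, and the overlap with a replicate block or without single libraries were chosen only after the data were seen. In AML12 the number of called genes stayed within 1.5 times of 5074 in every alternative except a 2-fold minimum, which left 41 genes at an adjusted and 44 at an unadjusted p below 0.05, since most changes were small. In iWAT a 2-fold minimum left 9 and 13 genes, no filter gave 664, a replicate block 503, voom 1992, and leaving out 1 library 511 (without DMSO replicate 3) to 687, against 1152. At an unadjusted p below 0.05 alone, 6247 AML12 and 3341 iWAT genes passed. No filter tests more genes and the left-out libraries reduce the sample, and for the block and voom the cause was not tested. Replicate numbers did not pair the libraries: correlations of same-number residuals lay between -0.0563 and 0.0289, all under 0.1 in size. Of the called lists, 7 of 14 in AML12 and 6 of 12 in iWAT held with an estimated correlation, and the cause was not tested. Without a filter AML12 hepatocyte markers (adjusted p = 0.0741) and iWAT adipocyte markers (0.148) lost their call, and AML12 PPAR alpha targets (0.0211), AML12 interferon response (0.00597), iWAT fatty acid and triglyceride synthesis (0.0369) and iWAT S phase and DNA replication (0.0149) gained one. The last also passed with quantile normalization (0.0388). By fry, which does not compare a list with other genes, the iWAT nuclear-encoded respiratory chain lost its call (0.106), while 6 AML12 lists and 4 iWAT lists gained one. Genes called in the same direction in both lines numbered 911 at an unadjusted p, 108 with a block, 584 with voom and 135 (without iWAT DMSO replicate 3) to 282 without 1 library, against 306, and exceeded expectation each time. The overlap of AML12 falls with iWAT rises (exact p = 0.0634) passed with median centring (exact p = 0.0374), quantile normalization (7.00e-05), a block (7.10e-05) and voom (0.00955), and in 7 of 12 fits without 1 library, whose exact p ran from 0.00339 (without AML12 DMSO replicate 2) to 0.3397 (without iWAT DMSO replicate 2). It did not pass with genes called at an unadjusted p (0.580), and the cause was not tested. The overlap of AML12 rises with iWAT falls (exact p = 0.615) passed only without AML12 DEP replicate 2 (0.0394). With a pseudocount of 0.01 the difference between the lines reversed for Klrg2 (0.56), Gbp2 (-0.49) and Acta2 (-0.39), all below the AML12 filter, where the small pseudocount magnifies single reads. A further 22 of the 94 named gene differences and 3 list differences lost their call there, and 11 and 1 did with a pseudocount of 0.1. The differences numbered 3545 to 4311 genes and 13 to 18 lists with an adjusted p, against 5869 genes at an unadjusted p below 0.05, and that of fatty acid and triglyceride synthesis lost its call in 7 alternatives. As deposited 60.9% of AML12 calls were rises, against 48.1% with median centring and 52.8% with quantile normalization, and in iWAT 47.1% were, against 37.8% with a block and 52.8% with voom. Among named genes none reversed within a line, and the only AML12 genes to lose a call were Mir192, Snord43 and Snord98. In iWAT these were Ephx1, Mir1964, Ndufa4, Plin2, Prr32, Scgb1a1, Snora47, Snord35a, Sqstm1 and Trib3, and Ddit3 and Fabp4 gained one under some alternatives. Alternatives chosen beforehand for deposited counts (other normalization factors, count-based tests and filters, and a side-by-side test) were not run, since the files hold FPKM. Depth limits genes of few reads: 1 read in a 1-kb gene was worth 0.0183 to 0.0233 FPKM.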

Other observations

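The gene families and single genes in the next 3 paragraphs, and the tests of families, were chosen only after the values were seen, while the histone test was chosen before its result.

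Families of genes sharing a symbol stem, with at least 8 tested members, were tested in AML12 beside the lists. The Ugt and Cyp families share members with the AHR, CAR and PXR lists, such as Ugt1a6b, Cyp1a1 and Cyp3a13. Of 20 nucleoporin genes (Nup), which build the nuclear pore and none of which was on a list, 16 rose and none fell (median 0.23, adjusted p = 9.47e-05, and adjusted p = 0.419 with an estimated correlation). Nup85, Nup93 and Nup107 rose by 0.55, 0.45 and 0.39 on the log2 scale. DEAD-box RNA helicase genes (Ddx) rose in 18 of 32 cases and fell in none, or in 1 with median-centred or quantile-normalized values (median 0.12, adjusted p = 0.0106), and splicing factor genes (Srsf) rose in 8 of 10 and fell in 1, or in none with quantile-normalized values (median 0.16, adjusted p = 0.0446). Centrosomal genes (Cep) rose in 15 of 34 cases and fell in 1 (median 0.15, adjusted p = 0.0135). Glucuronosyltransferase genes (Ugt) fell in 8 of 8 (median -0.79, adjusted p = 8.82e-06), though several share exons or sequence, and cytochrome P450 genes (Cyp) fell in 13 of 20 and rose in 2 (median -0.25, adjusted p = 0.000498). Of 167 families 20 were called in AML12, and with an estimated correlation 0 were, with 0.419 the lowest adjusted p.

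In iWAT, 4 of 186 families were called, all downward, and 0 with an estimated correlation, with 0.439 the lowest adjusted p. The Ifi, Ccl and Irf families share members with the interferon and inflammation lists, such as Ifi44, Ccl2 and Irf7. Interferon-inducible Ifi genes fell in 9 of 12 cases (median -0.48, adjusted p = 1.42e-08), with Ifi44, Ifi47 and Ifi204, a DNA sensor, at -0.79, -0.75 and -0.59. Poly(ADP-ribose) polymerase genes (Parp) fell in 6 of 12 cases (median -0.14, adjusted p = 0.000879), led by the interferon-induced Parp14 and Parp12 at -0.48 and -0.42. Chemokine genes (Ccl) fell in 4 of 9 cases (adjusted p = 0.000879) and interferon regulatory factor genes (Irf) in 3 of 9 (adjusted p = 0.0268).

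Genes called in the same direction in both lines included members of several lists. Of the genes that rose in both, 7 were p53 targets and 5 were S phase genes, among them Mcm3, a helicase subunit, at 0.65 in AML12 and 0.13 in iWAT, and the polymerase gene Pole at 0.68 and 0.12. Hmga2, a chromatin protein, rose by 0.65 and 0.24. Of those that fell in both, 4 were inflammation and 3 interferon genes, among them the adhesion gene Vcam1 at -0.53 and -0.36 and Bst2, which tethers virus particles, at -0.46 and -0.41. Complement C3 fell by 0.73 and 0.53 on the log2 scale, and Dhrs3, a retinal reductase, by 1.09 and 0.62. The counts per list were not tested for enrichment, and over the genes tested in each line the responses of the S phase and p53 lists differed between the lines (adjusted p = 1.87e-17 and 6.75e-07).

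A larger share of replicating cells in the DEP dishes was a hypothesis for AML12, tested on the replication-dependent histone genes, which no list held. Their rise was predicted, and a median under 0.1 was set to count against it. The median over 15 tested histone genes was -0.045 (quartiles -0.14 and 0.18), with 1 up and 3 down, and camera gave p = 0.219, or 0.260 with an estimated correlation. The predicted rise was thus not seen, and the result fell under the bound. The median level of these genes was 0.703 FPKM in DMSO and 0.887 in DEP, near the pseudocount, where the log2(FPKM + 1) scale shrinks any change. Whether that shrinkage was enough to hide a rise was not tested. A level of 5 FPKM was set as the least for a usable test only after the result was seen, so it does not undo the failed prediction. With genes at such low levels the hypothesis is not decided.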
